A study of Sus scrofa with 12 samples.

How the data were processed

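Longissimus dorsi, the long back muscle, was taken from 5-day-old pigs of 2 breeds, Large White and Ningxiang, and N6-methyladenosine (m6A) in its mRNA was mapped by methylated RNA immunoprecipitation and sequencing (MeRIP-seq). Per the labels' protocols, mRNA was isolated with oligo beads and fragmented, and fragments were enriched with an m6A antibody. A part of the fragmented mRNA was kept back as input, and libraries were built from both. The series has 12 samples, an immunoprecipitated one and an input one for each of 3 replicates per breed. The labels number the replicates and do not say whether each came from its own pig, so p-values measure the spread between these samples, which may be technical.

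The processed data were 6 deposited peak lists, 1 per replicate, so peaks were called per replicate and not on pooled samples. Each list was assigned to its immunoprecipitated sample, because the description of that sample and of the matching input names the same list. Per the file headers, each peak carries its position, the blocks of exon sequence it spans, a fold enrichment and a p-value with its log10 and adjusted forms, followed by gene annotation columns. The submitters' processing notes name FastQC 0.11.9, ChIPseeker 1.30.2, HOMER and the build susScr11. The aligner and the peak caller are not given in the sources used here. The deposited fold is a linear ratio of immunoprecipitated over input signal for the peak. Per the file headers, the p-value and its log10, the score by which peaks were ranked here, belong to the same peak. Fold and p-value are the authors' own values for a peak; they were used to describe, rank and filter peaks within a list and never to compare the level of methylation between breeds. The weakest peak over all lists had a p-value of 0.00871, the highest adjusted p-value was 0.0437 and the lowest fold was 1.53. Sequencing depth is unknown from these lists, and the input and immunoprecipitated read counts were not analysed here.

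Several properties of the files affect the measurements. Starts count from 0: 441 peaks begin 1 base before the start listed for their gene and 4 begin on it, so starts are printed here after adding 1. The deposited width is the genomic span, introns included. A peak that crosses a splice junction can therefore span long introns while covering few exonic bases, and both measures were computed. Every peak was annotated to an exon or an untranslated region of a curated RefSeq transcript, so adding intergenic peaks or keeping only exonic ones leaves every result as it is. Genes without such a transcript cannot carry a peak in these lists. RefSeq names on Sscrofa11.1 gave 3986 genes with a curated transcript, and 2135 of the 2159 genes with a peak were matched to that table by transcript. Exon numbers in the annotation rise along the chromosome on both strands: this held for 436 of 436 transcripts on the plus strand and 538 of 538 on the minus strand that had peaks in 2 or more exons. Minus-strand numbers were therefore turned round, so that exons count from the 5′ end of the transcript. The untranslated-region classes also differed by strand, with 28.9% of plus-strand peaks and 3.65% of minus-strand peaks listed in 3′ untranslated regions. Minus-strand peaks listed in 5′ untranslated regions lay at a median of 88.4% of the gene length from the 5′ end, against 24.0% on the plus strand. Class shares are therefore also given for plus-strand peaks alone, a choice made after this was seen, and the untranslated-region class of a single minus-strand peak is not used.

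Peaks, genes with a peak, covered length, median width and class shares per replicate were compared between breeds with exact two-sided permutation tests. With 3 replicates against 3 the smallest two-sided p such a test can give is 0.1, so no single comparison can pass 0.05. Benjamini-Hochberg adjustment was applied over the 7 comparisons together, a departure from the plan, which named the 3 classes alone. Over those classes the adjusted p of the exact permutation test was 0.6 for 3′ untranslated regions and 0.6 for exons. Overlap between 2 lists was the Jaccard index of the covered bases from bedtools 2.31.1, with an overlap of at least 1 bp counted as shared. The mean of 6 within-breed pairs was set against the mean of 9 between-breed pairs in a one-sided exact test over the 10 splits of the lists. A breed-only gene was one with a peak in 3 of 3 replicates of one breed and 0 of 3 of the other; the same rule was applied to merged genomic regions. The gene of a peak was the nearest gene the files list. Fisher's exact test (SciPy 1.17.1) compared 25 gene lists with the breed-only genes, against all 2159 genes with a peak. Python 3.11.15, pandas 2.3.3 and NumPy 2.4.6 were used. The counting of breed-only genes was checked on simulated lists of 2159 genes: 100 of 100 genes planted in Large White and 100 of 100 planted in Ningxiang were found, among 111 and 110 genes called. Planted genes met the rule by design, so the simulation checks the code and not how often real peaks are missed.

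Apart from the set of comparisons adjusted together, the groups, tests, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule names list members that are breed-only, the m6A writers, erasers and readers with a peak, and the 10 breed-only genes per breed with the highest minimum over their 3 replicates of the best peak's fold. It also names the 10 genes with the highest such minimum over all 6 lists. The best fold of a gene in a replicate is the highest fold among its peaks there, while the strongest peak, whose position is printed, is the one with the lowest p-value. Other genes lie beyond the rule and were chosen after their values were seen. The alternatives left out each replicate in turn, used the replicate number as a block, took the stronger 50% of each list by p or the same number of peaks from each list (2034, the best by p), asked for a reciprocal overlap of 50%, took the gene named in the annotation text, accepted 2 of 3 replicates, and weighted class shares by bases. Alternatives added after seeing the data were exonic blocks in place of genomic spans, the gene identifier written by the peak caller, plus-strand peaks alone, and the same number of peaks for covered length and width. The search for the m6A sequence motif and for peaks near stop codons needs a genome and coding annotation of this build and was not run.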

Results

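N6-methyladenosine peaks were listed for longissimus dorsi of 5-day-old Large White pigs, a breed selected for lean growth, and Ningxiang pigs, a Chinese indigenous breed, with 3 replicates per breed. The question of the study is which modified mRNAs are involved in muscle development in the 2 breeds. The 6 lists held 13487 peaks. Large White lists held 2373, 2214 and 2533 peaks, and Ningxiang lists 2034, 2111 and 2222. Peaks fell in 2159 genes, of which 771 had a peak in all 6 lists and 394 in 1 list only. Sequencing depth is unknown from these lists, so a gene without a listed peak was below the authors' calling threshold, which does not show that it lacked m6A.

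Of the fixed lists, 8 of 14 myogenic regulators and 12 of 19 sarcomere genes with any peak had one in all 6 lists, while MYOD1 and ACTC1, among others, had none in Large White. Peaks in all 6 lists were found on MYOG, a transcription factor of muscle differentiation, on MEF2A and MEF2C, which act with it, and on MSTN, the secreted inhibitor of muscle growth. The same held for the fast myosin heavy chains MYH1, MYH2 and MYH4, for DES, the muscle intermediate filament, for TPM1 and TPM2, the tropomyosins, and for RYR1, the calcium release channel of the sarcoplasmic reticulum. Best folds were low for DES (1.73 to 1.91), TPM1 (1.78 to 2.05) and TPM2 (1.76 to 1.94), where list medians over all peaks were 2.42 to 2.605. Those of MYH1, MYH2, MYH4 and RYR1 reached 3.32, 5.64, 3.65 and 3.82. Of 24 adipogenesis and lipid genes with any peak 12 had one in all 6 lists, and of 7 mitochondrial genes 1, PPARGC1A, a coactivator of mitochondrial gene expression. The 12 included PPARG, the regulator of fat cell formation, and CPT1A, which admits fatty acids to mitochondria. These genes were picked as examples from the fixed lists after their counts were seen. The best peak of MYOG had a fold of 2.61 ± 0.331 (SD, n = 3) over input in Large White, and 2.62 ± 0.360 (SD, n = 3) in Ningxiang, given here as the authors' values for each list and not as a comparison of methylation level.

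By the fixed rule, the genes with the highest minimum best fold over all 6 lists included SLC7A1, F5, EGR2, MDC1, AUTS2, TET1, PCDH7, SMN1 and MTF1. SLC7A1, a transporter of cationic amino acids, led them: its highest fold in a list ranged from 6.30 to 33.7. Its Large White peak with the lowest p lay at chromosome 11, 6541497 to 6541976 (susScr11), in exon 13 of 13 of the minus-strand gene. F5, which encodes a coagulation factor, ranged from 5.89 to 33.9, with a peak at chromosome 4, 81458248 to 81459296, in exon 13 of 25. EGR2, a zinc-finger transcription factor, ranged from 5.79 to 14.9. TET1, an enzyme that oxidises methylcytosine in DNA, ranged from 5.19 to 31.8. MDC1, a DNA damage mediator, did not fall below 5.53, AUTS2 below 5.22 and PCDH7, a protocadherin, below 4.87. SMN1, which assembles small nuclear ribonucleoproteins, did not fall below 4.83, and MTF1, the metal-responsive transcription factor, below 4.81. Some of these folds belonged to peaks weak by p. In Ningxiang replicate 2 the SLC7A1 peak had a log10 p of -3.29 and EGR2 -3.76, where the list median was -10.1. F5 had -3.47 in Ningxiang replicate 1, where the median was -9.465. With only the stronger peaks of each list by p, SLC7A1, F5, EGR2, TET1 and MTF1 were not in every list. MDC1, AUTS2 and SMN1 had -28.8, -24.7 and -57.5 or lower in every list.

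Of the m6A machinery, 3 of 24 listed members had a peak in any list, and 5 of the 24 have a curated transcript that could carry one. FTO, an m6A demethylase, and WTAP, a subunit of the methyltransferase complex, had peaks in 3 of 3 replicates of each breed. ELAVL1, an RNA-binding protein that stabilises transcripts, had one in 1 of 3 replicates of each. Taking the peak with the lowest p as the strongest, WTAP had its strongest Large White peak at chromosome 1, 7630374 to 7642870, over 655 exonic bases, and FTO at chromosome 6, 31343264 to 31388950, over 179 exonic bases. The number of members with a peak was 2.33 ± 0.577 (SD, n = 3) in both breeds.

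Peak number and gene number overlapped between the breeds, while the genomic span of peaks did not. Large White lists held 2373 ± 159.5 peaks (SD, n = 3) on 1466 ± 83.9 genes and Ningxiang lists 2122 ± 94.5 peaks on 1367 ± 68.4 genes (exact permutation test, two-sided p = 0.2 for each, adjusted p = 0.28). The median genomic span was 798 ± 72.3 bp in Large White and 602 ± 31.6 bp in Ningxiang, with every Large White value above every Ningxiang value (exact permutation p = 0.1, the smallest possible with 3 against 3; adjusted p = 0.28). From 54.0% to 59.3% of the peaks in a list crossed a splice junction. A small shift in that share can therefore move the median span, so it does not show that peaks in general were longer. Peaks covered 13258 ± 636 kb of genomic span in Large White and 10218 ± 461 kb in Ningxiang (exact permutation p = 0.1, n = 3 per breed, adjusted p = 0.28). Counted over exonic blocks alone, the median peak was 210 bp long in both breeds (210.3 ± 0.577 and 209.7 ± 0.577, exact permutation p = 0.6, n = 3), so the longer median span lay in introns crossed by the peaks. The exonic sequence covered in total was 650 ± 61.8 kb in Large White and 553 ± 37.5 kb in Ningxiang (SD, n = 3), with every Large White value above every Ningxiang value (exact permutation p = 0.1). With the same number of peaks from every list, the order of gene numbers turned round, to a difference of -23.7 genes for Large White minus Ningxiang (exact permutation p = 0.1).

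**Figure D1:**
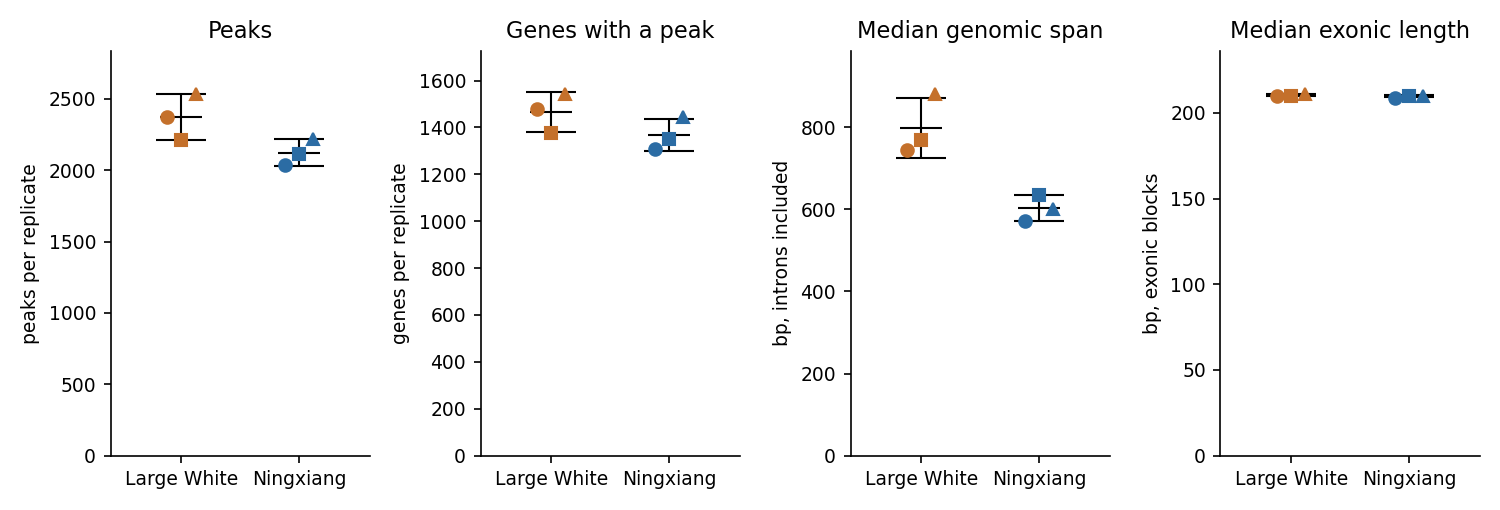
Peaks, genes with a peak, median genomic span and median exonic length of peaks (vertical axes, counts or bp, starting at 0) for Large White and Ningxiang; each symbol is 1 replicate, the same symbol shape marks the same replicate number, and bars show the mean and SD. The medians of genomic span lie between 745 and 880 bp in Large White and between 572 and 635 bp in Ningxiang, while exonic medians lie between 209 and 211 bp in both.

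More peaks lay near the 3′ ends of genes than near the 5′ ends in both breeds. Of all peaks, 35.4% ± 0.637 (SD, n = 3) in Large White and 35.7% ± 0.925 in Ningxiang had their midpoint in the last 10% of the gene's length, and 5.41% ± 0.263 and 6.25% ± 1.58 in the first 10%. Length here is genomic, introns included. The positions were not set against where exonic sequence lies in the same genes, so they do not show a preference of m6A. On the plus strand, where the classes follow the direction of transcription, 29.6% ± 1.25 of Large White peaks and 28.0% ± 0.943 of Ningxiang peaks were listed in 3′ untranslated regions (exact permutation p = 0.2, n = 3 per breed). Over both strands the listed share was 17.1% ± 0.518 against 16.1% ± 0.721 for 3′ untranslated regions (exact permutation p = 0.2, n = 3, adjusted p = 0.28) and 5.14% ± 0.512 against 5.27% ± 1.06 for 5′ ones (exact permutation p = 1, n = 3, adjusted p = 1). The 5′ difference changed sign when either the stronger 50% of each list by p or bases in place of peaks were used. Exons took 77.8% ± 0.496 and 78.6% ± 1.32 (exact permutation p = 0.4, n = 3, adjusted p = 0.467).

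Over genomic spans, Large White lists shared more sequence with each other than lists of different breeds did on average, while Ningxiang lists shared less. The mean Jaccard index was 0.365 ± 0.0414 (SD, 6 pairs) within breeds and 0.347 ± 0.0323 (SD, 9 pairs) between them, a difference of 0.0180 that is smaller than either SD (one-sided exact p = 0.1, the smallest that 10 splits allow). Large White pairs ranged from 0.384 to 0.413 and Ningxiang pairs from 0.320 to 0.341, all below the mean between breeds; pairs across breeds ranged from 0.291 to 0.398. Without Large White replicate 1 the sign turned, to -0.011, and without replicates 2 and 3 the difference was 0.00111 and 0.0096. Leaving out a Ningxiang replicate gave 0.0264 to 0.0439. With the same number of peaks from every list the difference was 0.0167 (one-sided exact p = 0.2). Over exonic blocks the mean was 0.429 ± 0.0266 within and 0.398 ± 0.0221 between breeds (SD; one-sided exact p = 0.1), and over genes 0.655 ± 0.0165 and 0.631 ± 0.0189 (SD; one-sided exact p = 0.1). Both of these differences, 0.0314 and 0.0238, exceed their SDs, and on both measures the Ningxiang mean, 0.407 and 0.645, also lay above the mean between breeds. Each list enters several pairs, so the pairs are not independent and none of these SDs measures the error of a difference.

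Genes with peaks in 3 of 3 replicates of one breed and 0 of 3 of the other included few members of the fixed gene lists: FASN, IGFBP2 and IGFBP3. FASN, the fatty acid synthase, had peaks in all 3 Ningxiang replicates and in no Large White replicate. IGFBP2 did the same, while IGFBP3 had peaks in all 3 Large White replicates and in no Ningxiang replicate; both bind insulin-like growth factors. In all, 29 genes were Large White only and 16 Ningxiang only. For a single gene, 3 of 3 against 0 of 3 has a two-sided p of 0.1 by Fisher's exact test, so none of these genes can be called different on its own.

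FASN carried its strongest Ningxiang peak at chromosome 12, 929480 to 929788 (susScr11), in exon 19 of 43; in replicate 3 its peak lay in exon 43. The best peaks of FASN had a mean fold of 2.66 ± 0.838 (SD, n = 3) over input. IGFBP2 had its strongest peak at chromosome 15, 118822445 to 118822563, in exon 1 of 4 in replicate 3, while the strongest peaks of replicates 1 and 2 lay in exon 2; its mean best fold was 3.50 ± 1.62 (SD, n = 3). Neither FASN nor IGFBP2 had an exonic region with a peak in all 3 Ningxiang replicates and none in Large White, so their replicates share the gene and not 1 site. Of the breed-only genes, 20 of 29 in Large White and 11 of 16 in Ningxiang had such an exonic region; RIOK1, RGS4, ADORA3, CAPN2, WDR62, PLIN3 and WIPI1 were also without one. IGFBP3 had its strongest peak at chromosome 18, 50003428 to 50006507, starting in exon 1 of 5, and a mean best fold of 2.79 ± 0.826 (SD, n = 3).

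Among the other Large White only genes taken by the fixed rule, RIOK1, a kinase of small ribosomal subunit maturation, had the highest mean best fold, 9.23 ± 6.47 (SD, n = 3). In replicates 1, 2 and 3 its best folds were 16.6, 6.6 and 4.49. RGS4, which switches off G-protein signals, had 7.75 ± 5.67, and RBP7, a retinol-binding protein, 4.15 ± 0.309. RNASEH2B, a subunit of the ribonuclease that removes RNA from DNA hybrids, had 5.44 ± 4.58. The means of RGS4 and RNASEH2B rest largely on replicate 3, with best folds of 14.3 and 10.7. Replicate 1 gave 4.56 and 3.2, and replicate 2 gave 4.4 and 2.41. ADORA3, an adenosine receptor, had 3.95 ± 2.17, and the annotation text gives another gene for part of its peaks, so its assignment is uncertain. NFKBIZ, a nuclear regulator of NF-kappaB target genes, had 3.04 ± 0.664, SPRYD3 2.84 ± 0.503 and GUCY1B1, a subunit of the nitric oxide receptor, 2.70 ± 0.417. LNPK, which shapes the endoplasmic reticulum, had 2.50 ± 0.0757 and PIGP, an enzyme of membrane anchor synthesis, 2.48 ± 0.215 (SD, n = 3 for each). RBP7 peaks lay at chromosome 6, the strongest from 70313433 to 70322890.

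Among the other Ningxiang only genes, WDR62, a spindle pole protein, had the highest mean best fold, 13.2 ± 5.09 (SD, n = 3). Its peaks were weak by p, with a lowest log10 p of -4.46, -4.2 and -3.13 in replicates 1, 2 and 3. The median peak of the Ningxiang lists had -9.465 to -10.1. NUBP2, an iron-sulphur cluster assembly protein, had 7.19 ± 5.64 and ELAC2, which trims transfer RNA precursors, 3.80 ± 0.972. NUBP2 reached 13.7 in replicate 3, against 3.73 and 4.14 in replicates 1 and 2. PMF1, a kinetochore protein, had 2.91 ± 0.350, LIN7B, a cell junction scaffold, 2.85 ± 0.229, and ARV1, a protein of sterol transport, 2.63 ± 0.267. PLIN3, a coat protein of lipid droplets, had 2.54 ± 0.312 and PM20D1, an enzyme that makes N-acyl amino acids, 2.57 ± 0.538 (SD, n = 3 for each). The Ningxiang set also held WIPI1 and WIPI2, which bind phosphoinositide on forming autophagosomes; these were named after the list was seen. WIPI2 peaks in all 3 replicates lay in the 3′ untranslated region, the strongest of replicate 3 from 3829475 to 3830604 on chromosome 3.

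**Figure D2:**
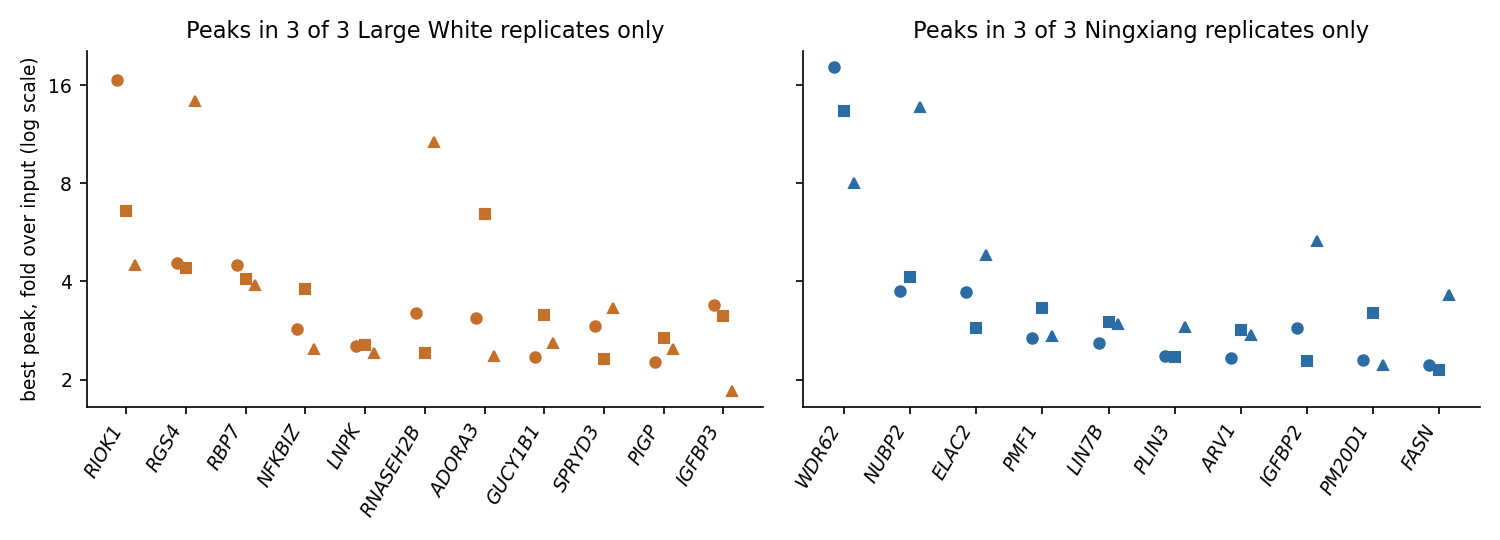
Highest fold over input among the peaks of a gene (vertical axis, log scale) of each breed-only gene named by the fixed rule, with Large White only genes on the left and Ningxiang only genes on the right; each symbol is 1 replicate and its shape the replicate number. RIOK1 and WDR62 reach the highest mean folds, 9.23 and 13.2, and FASN lies between 2.14 and 3.63.

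In 8 breed-only genes there was a best peak with a p-value of 1e-10 or lower in each of their 3 replicates, a limit set after the values were seen. In Large White these were CAPN2, a calcium-activated protease, CFL2, the actin-severing cofilin of muscle, HSPA6, a heat shock protein, and SUMO2, a small protein modifier. In Ningxiang they were FASN, GON7, MDH2, the mitochondrial malate dehydrogenase, and SERPINH1, the collagen chaperone. HSPA6 and SUMO2 belong to families with near-identical copies, so reads may be shared and their assignment is uncertain. CFL2 had a mean best fold of 1.83 ± 0.107, CAPN2 1.74 ± 0.0896, MDH2 3.39 ± 2.39 and SERPINH1 2.64 ± 1.64 (SD, n = 3). The means of MDH2 and SERPINH1 rest largely on replicate 3, with best folds of 6.15 and 4.53. Replicate 1 gave 2 and 1.73, and replicate 2 gave 2.01 and 1.65. Another split of the lists gave up to 6 genes with such peaks, so these 8 hardly stand out. With the stronger 50% of each list by p the same 8 remained of the 45 breed-only genes, which is nearly the same filter and no separate support. That cut gave 24 Large White only and 9 Ningxiang only genes, most of them not breed-only with all peaks.

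With the same number of peaks from every list, 21 of the 29 Large White only genes and 13 of the 16 Ningxiang only genes remained. The totals became 23 and 28, so the order of the breeds turned round. ADORA3, RGS4, NFKBIZ, WDR62, PM20D1 and WIPI1 were the named genes that dropped out, while FASN, IGFBP2 and IGFBP3 stayed. With the stronger 50% of each list by p, only 1 of the 21 breed-only genes named by the fixed rule remained, FASN. IGFBP2 and IGFBP3 were lost there. With all peaks, 60 regions were Large White only and 34 Ningxiang only, and with the same number of peaks from every list 50 and 47, so most of the Large White excess in regions was absent at equal list length. Counted over exonic blocks with all peaks there were 166 and 64.

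**Figure D3:**
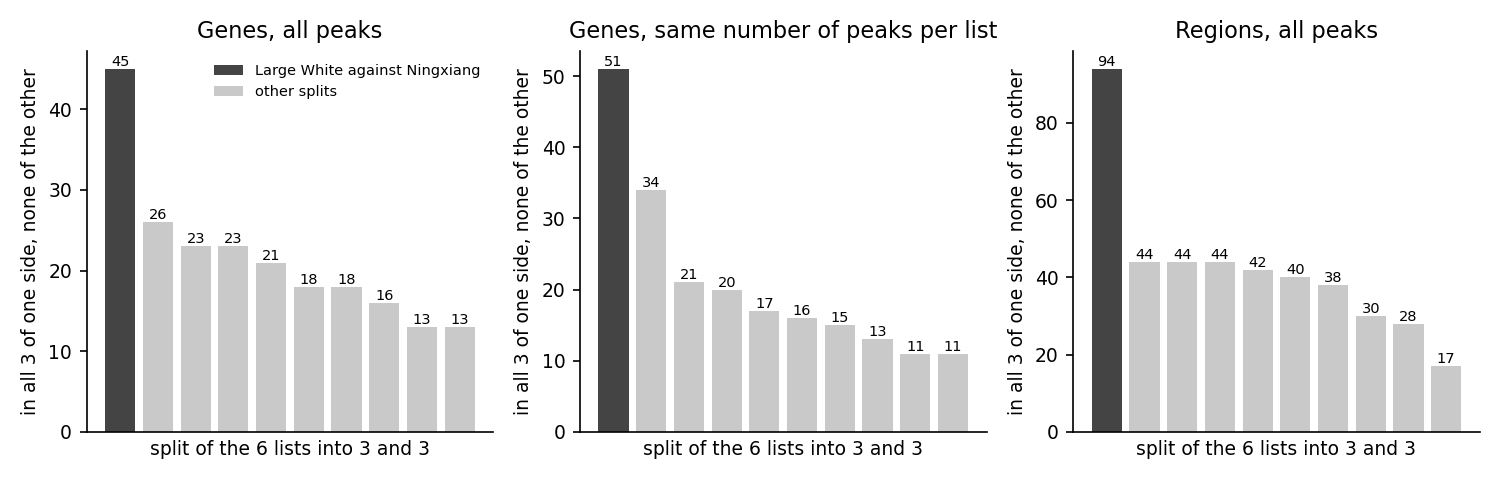
Genes or regions with a peak in all 3 lists of one side and none of the other (vertical axis, count) for each of the 10 splits of the 6 lists into 3 and 3, ordered by height; the dark bar is the split by breed. The breed split gives 45 genes, 51 genes with the same number of peaks per list and 94 regions, and the highest other split 26, 34 and 44.

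Many breed-only exonic regions lay in genes that had peaks in both breeds. The split by breed gave 230 such regions, and other splits of the lists gave 68 to 129. A peak that crosses splice junctions can give several of them, so they are not separate sites. Some are short, such as the 21 bp of RYR1 in Large White. Of 108 genes with a Large White only exonic region, 54 had a peak in all 6 lists, and of 46 genes with a Ningxiang only one, 18 did. Members of the fixed lists among them, all named after their values were seen, included in Large White ACACA, the acetyl-CoA carboxylase of fat synthesis, CPT1A, PDGFRA, a receptor of fibro-adipogenic cells, and VCAN, a matrix proteoglycan. In Ningxiang they included IRS1, the insulin receptor substrate, HK1, a hexokinase, PLIN5, a lipid droplet protein of oxidative tissue, and COL5A1, a collagen chain. RYR1 had such regions in both directions, at chromosome 6, 47409855 to 47409875 in Large White and 47389967 to 47390060 in Ningxiang. The region of IRS1 lay at chromosome 15, 128304055 to 128304504, and covered 450 bp; that of HK1 lay at chromosome 14, 72460051 to 72460389.

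No fixed gene list was over-represented among breed-only genes. Over 25 lists and both breeds, 0 of 50 Fisher's exact tests had an adjusted p under 0.05 and 0 an unadjusted one; the lowest unadjusted p was 0.126, for insulin, IGF, AKT and mTOR signalling in Ningxiang, with 1 member, IGFBP2, of 18. Adipogenesis and lipid metabolism in Ningxiang rested on FASN, 1 of 24 members with a peak (Fisher's exact p = 0.164, adjusted p = 1).

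The number of list members with a peak per replicate did not separate the breeds in any of the 25 lists, where chance gives 10% of lists. The lowest exact permutation p was 0.2 (adjusted p = 1). Single members of any list given with their replicate counts, such as MYF6 or PGAM2, lie outside the fixed rule and were picked after their counts were seen. Of the 14 myogenic regulators with a peak in any list, 8 had one in all 6; the count was 10.3 ± 0.577 in Large White and 11.3 ± 2.31 in Ningxiang (SD, n = 3). MYF6, a late myogenic factor, had peaks in 3 Large White and 1 Ningxiang replicates, and MYOD1, an early one, in 0 and 2. Sarcomere genes counted 17 ± 1 and 15.7 ± 0.577, with TNNI2, the fast troponin I, in 3 and 1 replicates and ACTC1, the cardiac actin, in 0 and 2. Slow fibre genes counted 4.67 ± 1.53 and 3.67 ± 0.577, and fast fibre genes 9 ± 1.73 and 8 ± 1. Excitation-contraction coupling counted 7 ± 1.73 and 6.33 ± 0.577.

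In growth signalling, insulin, IGF, AKT and mTOR genes counted 15 ± 1 in both breeds, with FOXO1, IGF1R and IRS1 among the 10 members in all 6 lists. Counts for TGF-beta, BMP and activin genes were 16.7 ± 1.53 in Large White and 15.3 ± 2.08 in Ningxiang, for Wnt genes 5.33 ± 0.577 and 6 ± 1.73, and for Notch genes 2.33 ± 0.577 and 1.33 ± 0.577. DLL4, a Notch ligand, had peaks in 3 Large White and 1 Ningxiang replicates. Protein degradation and autophagy genes counted 8 ± 1 and 6 ± 1, with BECN1, which starts autophagy, in 2 and 0 replicates and ATG12 in 3 and 1. Cell cycle genes counted 9.67 ± 2.08 and 10.7 ± 0.577, and chromatin regulators 6.67 ± 0.577 and 7 (SD 0). Only 3 of the 19 listed Notch genes and 7 of the 49 chromatin regulators have a curated transcript that could carry a peak.

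In metabolism, adipogenesis and lipid genes counted 18.3 ± 3.21 in Large White and 18.7 ± 1.15 in Ningxiang. PLIN2, a lipid droplet protein, had peaks in 3 Large White and 1 Ningxiang replicates, and PNPLA2, the triglyceride lipase, in 0 and 2. Mitochondrial genes counted 3 ± 1 and 4.67 ± 1.53, with UCP3, a mitochondrial carrier, in 1 and 3 replicates and ESRRA, a nuclear receptor of oxidative metabolism, in 0 and 2. Glycolysis and glycogen genes counted 5 (SD 0) and 5.33 ± 0.577, with PGAM2, the muscle phosphoglycerate mutase, and HK1 each in 1 and 3. Extracellular matrix genes counted 13 (SD 0) and 13 ± 1.

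Markers of other cells in the muscle also carried peaks. Fibroblast and fibro-adipogenic markers counted 5.67 ± 1.15 in Large White and 5.33 ± 0.577 in Ningxiang, with DCN, LUM and PDGFRA in all 6 lists. Adipocyte markers counted 4.33 ± 1.53 and 3.67 ± 0.577, endothelial markers 5 (SD 0) and 4.67 ± 0.577, smooth muscle and pericyte markers 2 (SD 0) and 3 ± 1, immune markers 6.67 ± 0.577 and 5.67 ± 1.53, and nerve and Schwann cell markers 3 ± 1 in both. No erythroid marker had a peak, where 3 of the 10 listed have a curated transcript that could carry one. Satellite cell markers counted 3.67 ± 2.31 and 5.33 ± 0.577; Large White replicate 2 had a peak on 1 of the 6, SPRY1, and lacked one on MYF5, CD82, CXCR4, SDC4 and VCAM1, where the other replicates had 5 or 6.

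**Figure D4:**
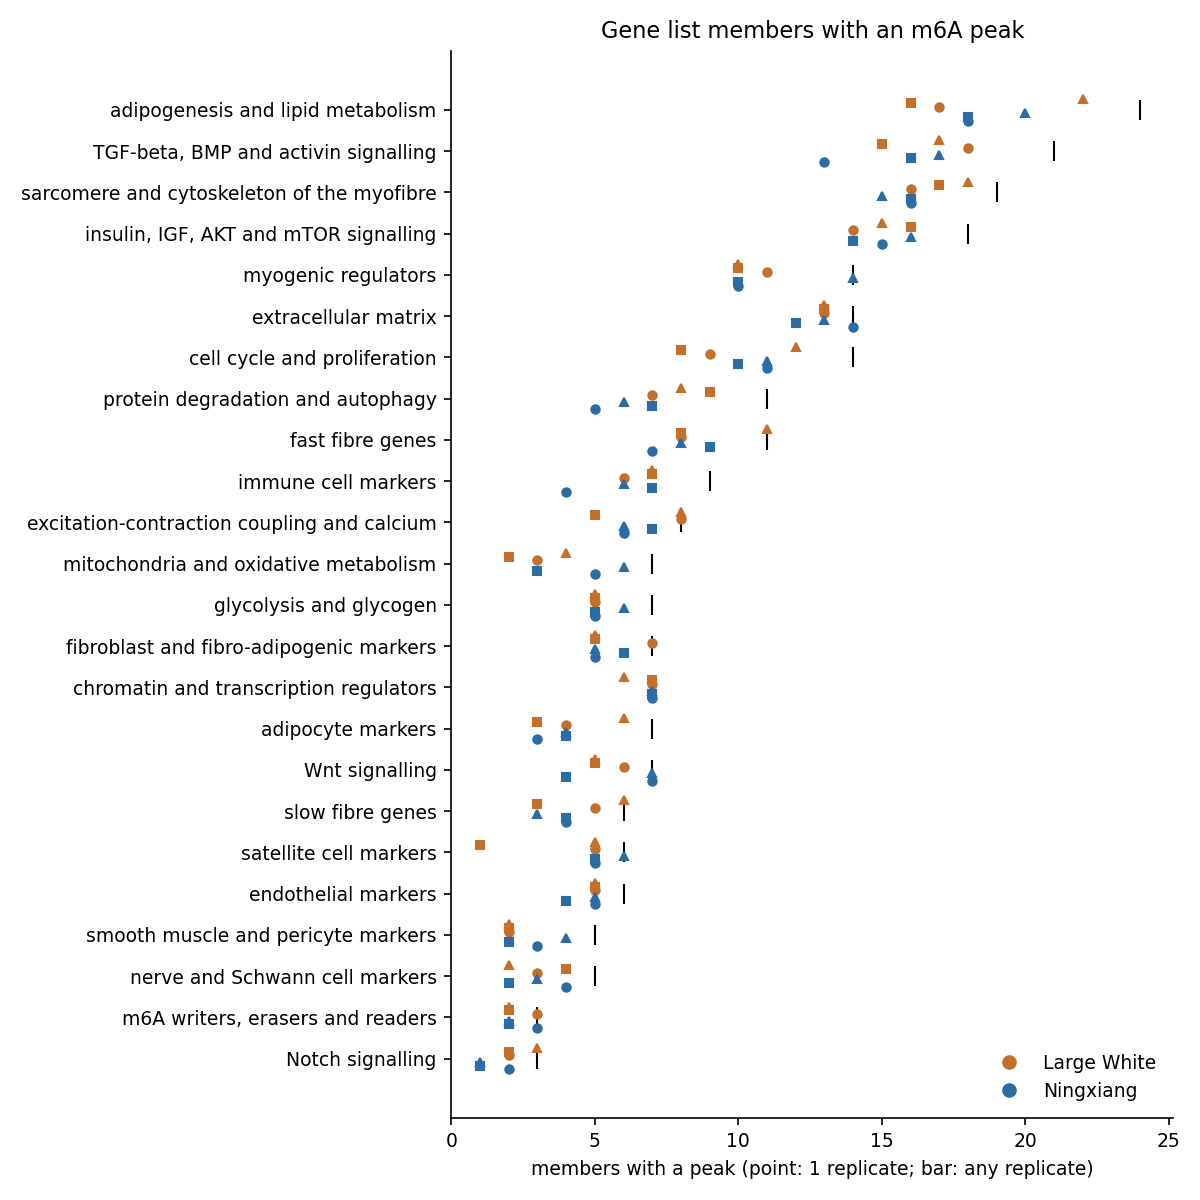
Members of each fixed gene list with a peak (horizontal axis, count) per replicate, in Large White (orange) and Ningxiang (blue); each symbol is 1 replicate, its shape the replicate number, and the vertical bar is the number of members with a peak in any replicate. The breeds overlap in every list shown, and Large White replicate 2 has 1 satellite cell marker where the others have 5 or 6.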

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

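The alternatives with exonic blocks, the gene identifier of the peak caller, plus-strand peaks, and the same number of peaks for covered length and width were chosen after seeing the data. No permutation test of 3 replicates against 3 can pass 0.05, so values were called moved when they shifted by more than 1 pooled SD, or a count by more than 1.5 times. Of 369 alternative values, 313 did not move, 44 moved and 12 changed sign; 225 of them are counts of single gene lists, of which 217 did not move. The motif and stop codon results and all their alternatives were not run. Adding intergenic peaks or keeping only exonic ones changes nothing by construction, since every peak is exonic.

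The difference in peaks per replicate stayed positive when each replicate was left out, from 171 to 331. The replicate block and the stronger 50% of each list keep its sign by construction. Gene number turned from 98.7 to -23.7 (Large White minus Ningxiang) with the same number of peaks. The difference in covered length was 1958 kb in the stronger 50% of each list by p, 2084 kb with the same number of peaks and 97.6 kb over exonic blocks, where the Ningxiang mean is 553 kb; that in median width was 287 bp with the same number of peaks and 0.667 bp over exonic blocks. Fewer peaks or bases lower covered length by construction; the cause of the larger width difference was not tested. The difference in 3′ untranslated share was 1.66 percentage points on the plus strand. That of the 5′ share changed sign in the stronger 50% (0.379) and by bases (0.121), and ranged from -0.584 to 0.455 when each replicate was left out. The overlap difference ranged from -0.011 (without Large White replicate 1) to 0.0439.

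Leaving out a replicate loosens the rule for breed-only genes and regions by construction: Large White only genes then ranged from 44 to 69, Ningxiang only genes from 22 to 41, Large White only regions from 98 to 133 and Ningxiang only regions from 45 to 94. Accepting 2 of 3 replicates gave 116 and 69 genes and 246 and 168 regions. The stronger 50% of each list gave 24 Large White only and 9 Ningxiang only genes, and 38 and 12 regions. Of these genes, 4 in Large White and 4 in Ningxiang were among the original 29 and 16. The same number of peaks gave 23 and 28 genes and 50 and 47 regions. A reciprocal overlap of 50% gave 59 and 40 regions, and exonic blocks 166 and 64. No gene list passed adjustment among breed-only genes in any alternative. Lists whose breeds did not overlap numbered 0 to 4 when each replicate was left out and 1 with the same number of peaks. Differences in list members changed sign when a replicate was left out for myogenic regulators (-1.67 to 0.333), adipogenesis and lipid metabolism (-2.17 to 0.833), fibroblast markers (-0.333 to 0.667) and adipocyte markers (-0.167 to 1.33).

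The replicate numbers do not pair the lists: deviations of same-numbered lists from their breed mean correlated over genes at 0.0222, 0.0133 and -0.0359, and not every list correlated best with its own number. With the replicate block, the paired difference was again 251 peaks and 195 bp of median span, with an exact sign-flip p of 0.25 for both, the smallest that 3 pairs allow; no call changed.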

Other observations

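Some fixed gene groups carried peaks far more often than the curated genes at large, a comparison added after the data were seen. All 14 myogenic regulators with a curated transcript had a peak in at least 1 list, against 53.4% of the 3986 genes with such a transcript (Fisher's exact adjusted p = 0.00225 over 25 lists). For TGF-beta, BMP and activin signalling 21 of 23 had one (Fisher's exact adjusted p = 0.00225), among them SMAD1, SMAD3, SMAD4 and BMP4, picked after their values were seen. For insulin, IGF, AKT and mTOR signalling 17 of 20 had one (Fisher's exact adjusted p = 0.0464). The other 22 lists did not pass. The background holds genes that muscle does not express and that cannot give a peak, and gene length and expression were not matched, so these values describe the lists and not a preference for m6A.

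The tests in the rest of this part were chosen only after the results were seen. The split by breed gave 45 genes with a peak in 3 lists of one side and none of the other, against at most 26 in another split, and 1 of the 10 splits gave as many; for regions it gave 94 against at most 44, again 1 of 10 splits. With 10 splits no share under 0.05 can be reached. Longer Large White lists as the cause of the total are left undecided. With the same number of peaks from every list the total was 51, against at most 34 in another split. That cut takes weak peaks mostly from Large White lists, which can itself make Ningxiang only genes. Of the 28 Ningxiang only genes it gave, 13 were among the original 16, and in Large White 21 of 23 were original. Peaks near the calling threshold stay open as an explanation: the weakest best peak of these genes had a median log10 p of -4.49, against -4.38 for 171 other genes with peaks in exactly 3 lists (permutation test, p = 0.933) and -10.7 for genes in all 6. A difference between breeds in m6A or in transcript level also remains open and untested, since input levels were not analysed here.

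The longer genomic span of Large White peaks did not come from different genes in the lists as its whole cause: within the 771 genes with peaks in all 6 lists the medians still differed by 153 bp, with every Large White value above every Ningxiang value (exact permutation p = 0.1, n = 3 per breed). Longer Large White lists are left undecided as a cause. With the same number of peaks per list the difference was 287 bp, but that cut drops weak peaks mostly from Large White lists. It raised the Large White medians from 745, 767.5 and 880 bp to 889.5, 838.5 and 1049 bp. Ningxiang replicate 1, left whole, stayed at 572 bp, and the other Ningxiang medians rose from 635 and 600 bp to 656.5 and 688 bp. Peaks that cross a splice junction made up 57.7% ± 1.41 (SD, n = 3) in Large White and 55.1% ± 1.41 in Ningxiang over all peaks, with overlapping values (exact permutation p = 0.2), and 56.7% ± 1.11 and 54.5% ± 0.732 within the shared genes (exact permutation p = 0.1). The share of such peaks, sequencing depth, fragment length and a breed difference may each contribute to the longer median span and were not tested.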
